A study of Saccharomyces cerevisiae with 11 samples.

How the data were processed

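The study tested designed 20-residue peptides as transcriptional activation domains in Y2H Gold, a yeast reporter strain in which activation gives resistance to the antifungal aureobasidin A. A pooled library was grown with or without the antibiotic, and the abundance of each designed sequence was measured by sequencing DNA recovered from the cells. The 11 samples are the culture at 0 h, untreated cultures at 12 and 24 h, and cultures labelled 150 and 200 aureobasidin at 12, 24, 48 and 72 h. Each sample has 5 barcoded sub-libraries, which makes 55 columns of values, and the series text calls these barcodes biological replicates. Nothing in the labels says that they were separate cultures. The p-values below therefore measure spread between barcoded sub-libraries, except those of the set test camera, described below. The dose is printed without a unit here because the labels contradict each other: the sample fields give mM, whereas the growth protocol gives a mass per volume. That protocol also describes growth with antibiotic for every sample, the untreated ones included; groups were taken from the titles.

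Per the labels' protocols, the designed pool was synthesised, amplified with primers that added the replicate barcodes, cloned, and recovered from yeast DNA by PCR. The submitters' processing notes name cutadapt and STAR, with no version and no role for either. The deposited values are raw read counts per designed sequence and barcode, per the file headers and the values themselves, which are whole numbers. How reads were assigned to sequences is stated in neither the labels nor the headers. No genome was needed. The table holds 12400 library entries in 143 design sets, of which 153 entries begin with a stop codon and 4 encode 21 residues. The others encode 12142 distinct peptides, and 146 of these entries share their peptide with another entry. Total counts per library ran from 683589 to 3392656, with 96472307 counts in all, and no pair of libraries was identical. A floor of 3 counts over the 5 libraries of a group was used for sequences with no read. Such floors cover counting error only, because PCR reads without molecular identifiers are not independent molecules.

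The comparisons, tests, alternatives and the rule for naming sequences were fixed before the data were examined. The 13 comparisons of groups used the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (two-sided) on the counts, scaled to total counts, with only the 2 groups compared in each fit. Total-count scaling asks whether a sequence gained or lost share of the pool. Sequences with a mean of at least 10 counts over the 10 libraries were tested, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM stands for reads scaled to a common library total of 1e+06. Alternatives were TMM factors, DESeq2 1.42.0 with its own size factors, no filter, a minimum mean of 50, the barcode number as a replicate block, all groups in 1 fit, and leaving out each barcode in turn. An alternative added after the data had been seen took off, from the libraries labelled 200 at 24, 48 and 72 h, a share of reads spread like the 0 h pool, estimated by assigning every stop-first read to such material. This assumes reads in proportion to the 0 h pool, which sequences with over 200 reads at 0 h in a barcode did not follow. The pairing of barcode numbers was checked on deviations of log2 CPM from the mean of the 5 barcodes of each group. These deviations correlated between groups at 0.43 to 0.956 for the same number and at no more than -0.089 for other numbers. Taking off the group mean itself makes values between different numbers tend to be negative. The best match was the own number for 5 of 5 barcodes in every comparison.

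Sequence features were compared as the mean log2 CPM (prior count 2) of the peptides above the library median of a feature minus that of the peptides below it. The 5 values at 72 h were set against the 5 at 0 h in a two-sided exact permutation test, whose smallest p is 0.00794, adjusted over the features. Features and 130 design sets were also tested with camera of limma 3.58.1, with a preset correlation of 0.01 and with an estimated one. Camera compares the changes of a set with those of other sequences, so its p-values also measure spread between sequences. For a design set these are all other tested sequences, and for a feature the peptides on the other side of the split. Its up and down are relative to them and need not mean a gain or loss of share. These were sets with at least 5 members and the control and stop-first sets, where any member was tested. Control activation domains had 4 entries each, of which as few as 2 were tested. The agreement of the doses was set beside 20 simulations of unchanged groups sharing the 0 h libraries and beside a split of those libraries.

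Named sequences follow a rule. For the label 200 at 72 h it takes the 12 largest rises and 6 largest falls past the threshold, moving the same way in all 5 barcodes and with a mean of at least 10 reads at 0 h. For the label 150 it takes 6 rises and 3 falls. It adds the 5 largest shares at 72 h at each dose, 4 each way between the doses, 3 each way in untreated cultures at 24 h, and the control peptides in file order, up to 10. The comparisons of substitution series with their parents, of the 32 sets built from 4 residues, of flanking residues and of peptides with equal composition were added after the data had been seen. Measures from the summed reads of a set were also added then, because the planned mean of logs is limited at low counts and gave directions that differ from those of the summed reads. Effective number is the inverse of the sum of squared shares. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

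The fits were tested on simulated data with 200 changed sequences, far fewer than were called in the data. Each fit had its own simulated counts. Those for the fit without a block had no barcode effect, with a dispersion of 0.843 (label 200 at 72 h) or 1.13 (untreated at 24 h). Those for the blocked fit had an assumed barcode effect, with a dispersion of 0.12 or 0.161. The numbers found therefore do not rank the fits. For the label 200 at 72 h, the fit without a block found 3 of 50 sequences changed 4-fold, 15 of 50 changed 8-fold, 49 of 50 raised 32-fold and 42 of 43 lowered 32-fold, with 4 false calls among 8552 unchanged sequences. With the replicate block it found 50 of 50 at each size, with 7 false calls among 8555. For untreated cultures at 24 h the fit without a block found 1, 8 and 35 of 50 raised 4-, 8- and 32-fold and 31 of 42 lowered 32-fold, with 0 false calls among 8762, and the blocked fit found 48, 50 and 50 of 50 and 46 of 46, with 6 false calls among 8779. The 32-fold size was included after smaller changes had been missed without the block. For features a planted difference of 1 was estimated at 0.89 to 0.96.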

Results

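DNA sequencing followed a library of designed activation-domain peptides through growth of reporter yeast with and without aureobasidin A, in 11 samples of 5 barcoded libraries each. The mean total count per library was 1551690 ± 357575 (SD, n = 5) at 0 h, with the lowest group mean, 971570 ± 242605, at 24 h with the label 200 and the highest, 2562648 ± 722164, at 72 h with that label. Summed over 5 libraries, the groups held 4857852 to 12813242 counts, so that 3 counts correspond to between 0.618 and 0.234 CPM. The doses are given as the labels' numbers, 150 and 200, because the labels contradict each other on the unit.

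The library narrowed with time in every arm and most under the antibiotic. The effective number of sequences was 1600 ± 117 at 0 h, 726 ± 76.7 in untreated cultures at 24 h, 53 ± 13.4 at 72 h with the label 150, and 21.6 ± 7.06 at 72 h with the label 200 (SD, n = 5 each). The most abundant sequence of a library held 0.504 ± 0.148% of its reads at 0 h, 10.9 ± 3.22% at 72 h with the label 150 and 19.6 ± 5.41% with the label 200. Entries whose first codon is a stop, which encode no peptide, made up 0.4 ± 0.0265% of reads at 0 h and 0.0287 ± 0.00676% in untreated cultures at 24 h. At 72 h with the label 150 they had no read, which allows up to 0.302 CPM, whereas with the label 200 they still held 0.00428 ± 0.00134%. A read was seen for 11400 ± 149 entries at 0 h, 1990 ± 71.9 at 72 h with the label 150 and 5020 ± 510 with the label 200.

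**Figure D1:**
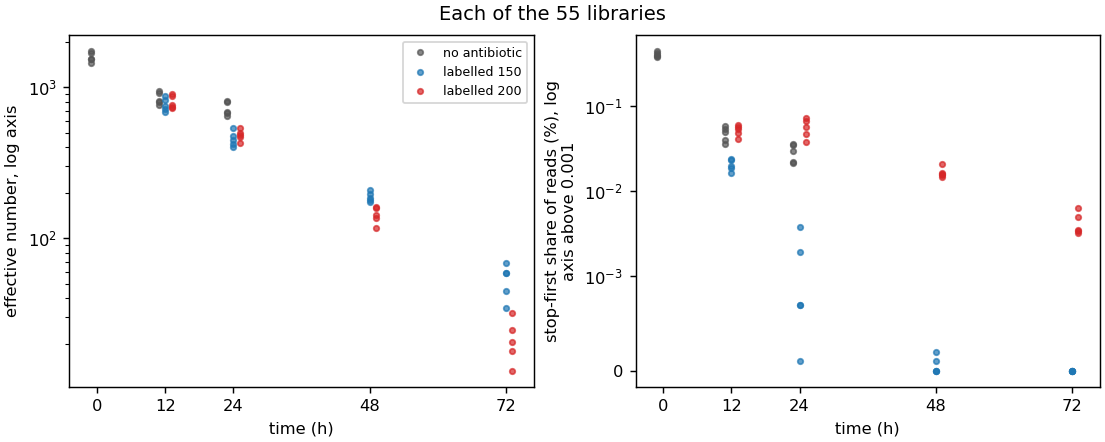
Effective number of sequences (log axis) and share of reads from stop-first entries (percent, axis logarithmic above 0.001) against time in hours, with a point for each of the 55 libraries, coloured by arm. The effective number falls from a mean of 1600 at 0 h to 53 and 21.6 at 72 h with the labels 150 and 200.

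Untreated cultures against 0 h ask how the library drifts with no antibiotic. Entries that encode no peptide were among those that lost share by 12 h: of 126 stop-first entries tested at 12 h, 80 fell and 0 rose, with a median log2 change of -3.33, and at 24 h 99 of 124 fell, with a median of -4.13, also when the 2 entries with no read left are set at their bound. Their median abundance went from 19.4 ± 1.54 CPM at 0 h to 1.13 CPM at 12 h. Sets of peptides with 1 hydrophobic core lost share in a like degree: between 0 h and 12 h stop-first entries went from 0.4% to 0.0471% of reads, phenylalanine cores from 0.382% to 0.0492%, leucine cores from 0.415% to 0.0548%, tyrosine cores from 0.383% to 0.0544% and tryptophan cores from 0.520% to 0.0901%. Variants with every tryptophan replaced by tyrosine fell in 20 of 89 tested at 24 h, against 0 with TMM scaling, 11 with DESeq2 and 89 with the block. The control activation domains, Oaf1 and the doubled VP16 peptide aside, fell in 12 of 77, with a median log2 change of -1.06 that TMM scaling turns to 0.21 and DESeq2 to 0.11. The named falls at 24 h were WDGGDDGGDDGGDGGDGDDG, at least 161-fold lower, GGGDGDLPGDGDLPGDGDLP, at least 128-fold lower, and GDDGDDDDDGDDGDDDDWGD, at least 113-fold lower. The edgeR adjusted p was 0.00633 for each. All were lower in 5 of 5 barcodes, which the naming rule requires.

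In all, edgeR called 2420 of 9115 sequences lower at 12 h and 2399 of 9000 at 24 h. It called 0 higher at either time, also 0 at an unadjusted p under 0.05, where DESeq2 called 81 higher and 712 lower at 12 h and 92 higher and 1548 lower at 24 h, and TMM scaling 0 and 0, then 0 and 357. With the replicate block the calls were 1014 higher and 6480 lower at 12 h and 821 higher and 6714 lower at 24 h; among those higher, 0 and 16 had risen at least 2-fold. The stop-first entries that fell at 12 h numbered 0 with TMM scaling, 27 with DESeq2 and 126 with the block. The calls at 12 h numbered 1188, 1275, 693, 1729 and 1104 without barcodes 1 to 5 in turn, and those at 24 h 1429, 1466, 1085, 1796 and 1396. TMM scaling shifts the median log2 change by 1.26 at 12 h and 1.25 at 24 h, and DESeq2 shifts it by 1.33 and 1.1.

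After 72 h with the label 200, the largest rises lay mostly in peptides in which leucine, methionine or proline replaces glycine. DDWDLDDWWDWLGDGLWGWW went from 0.1084 ± 0.02734% of reads at 0 h to 0.7178% at 24 h, 4.397% at 48 h and 19.49 ± 5.707% at 72 h, a 180-fold rise (log2 7.49, SE 0.79, edgeR adjusted p = 4.54e-10). In untreated cultures it stood at 0.2136 ± 0.0751% at 24 h. The peptide with methionine at the same 3 positions, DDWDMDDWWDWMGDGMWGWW, rose 33.6-fold (log2 5.07, SE 0.81, edgeR adjusted p = 1.71e-07). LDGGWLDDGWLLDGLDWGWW rose 65.9-fold (log2 6.04, SE 0.88, edgeR adjusted p = 4.22e-08) and the proline-bearing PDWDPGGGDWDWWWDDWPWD 37.4-fold (log2 5.22, SE 0.86, edgeR adjusted p = 2.62e-07).

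Of the 12 named rises at this label, 8 were glycine-to-leucine variants, 1 a glycine-to-methionine variant, 1 a glycine-to-proline variant and 2 were entries of the tryptophan and aspartate control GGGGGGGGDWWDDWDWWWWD, which rose 39.1- and 32.5-fold. The remaining leucine variants were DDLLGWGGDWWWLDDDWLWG (34.3-fold), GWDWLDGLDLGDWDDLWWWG (26.5-fold), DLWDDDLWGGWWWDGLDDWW (25.7-fold), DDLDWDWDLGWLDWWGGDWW (21.1-fold), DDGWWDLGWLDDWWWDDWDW (20.9-fold) and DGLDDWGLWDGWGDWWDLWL (20.7-fold). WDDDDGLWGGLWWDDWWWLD, named for its share of reads, rose 17-fold. The 6 named falls had no read left: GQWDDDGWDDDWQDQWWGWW was at least 1970-fold lower, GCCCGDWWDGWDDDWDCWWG at least 1470-fold, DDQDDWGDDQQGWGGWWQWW at least 1180-fold, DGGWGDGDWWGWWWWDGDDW at least 1040-fold, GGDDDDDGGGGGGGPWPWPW at least 1010-fold and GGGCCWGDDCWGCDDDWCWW at least 956-fold, with edgeR adjusted p from 6.64e-09 to 1.46e-08. Each of these rises and falls went the same way in 5 of 5 barcodes, which the naming rule requires except of peptides named for their share.

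With the label 150 at 72 h the same leucine peptide led: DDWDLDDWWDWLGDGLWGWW reached 10.76 ± 3.425% of reads, a 99.3-fold rise (log2 6.63, SE 0.68, edgeR adjusted p = 3.75e-06). It was higher in 5 of 5 barcodes, which the naming rule requires of a rise. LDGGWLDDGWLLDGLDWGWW rose 38-fold, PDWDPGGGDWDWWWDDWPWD 30.6-fold, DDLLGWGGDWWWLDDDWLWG 27.7-fold, the fourth entry of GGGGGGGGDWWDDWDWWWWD 26.7-fold and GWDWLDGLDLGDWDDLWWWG 24-fold. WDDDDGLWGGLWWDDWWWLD and the methionine variant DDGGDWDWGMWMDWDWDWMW, named for their shares, rose 21.2- and 16.1-fold. The named falls were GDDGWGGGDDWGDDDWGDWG, at least 4550-fold lower, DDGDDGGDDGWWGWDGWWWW, at least 2730-fold, and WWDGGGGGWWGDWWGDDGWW, at least 2470-fold.

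**Figure D2:**
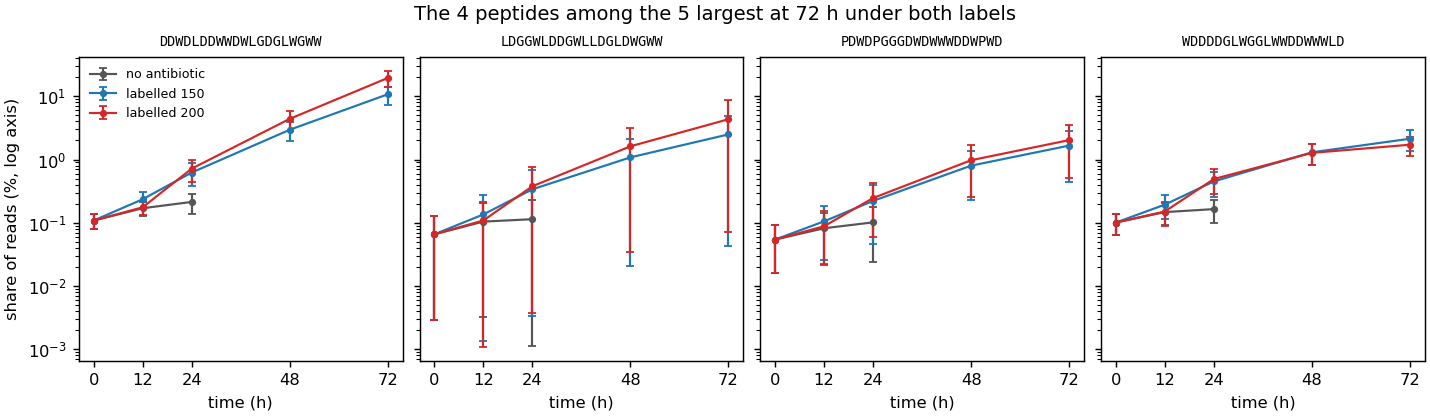
Share of reads (percent, log axis) against time in hours for the 4 peptides among the 5 largest at 72 h under both labels, as means with SD over 5 barcodes, without antibiotic and by dose label. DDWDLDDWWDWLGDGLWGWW climbs from 0.1084% at 0 h to 19.49% at 72 h with the label 200.

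Across the library, losses outnumbered gains at each time under the antibiotic. With the label 150, edgeR called 0 sequences higher and 4857 lower of 8884 at 12 h, 66 and 6326 of 8719 at 24 h, 190 and 7227 of 8708 at 48 h, and 171 and 7711 of 8703 at 72 h. The rises at 24, 48 and 72 h became 159, 516 and 436 with TMM scaling, 190, 511 and 426 with DESeq2, and 653, 619 and 391 with the replicate block. With the label 200 edgeR called 0 higher and 3103 lower of 9127 at 12 h, 41 and 3557 of 9000 at 24 h, 220 and 7486 of 8853 at 48 h, and 165 and 7986 of 8755 at 72 h. The counts of 0 were also 0 at an unadjusted p under 0.05, whereas DESeq2 called 204 higher and 3971 lower at 12 h with the label 150 and 760 higher and 0 lower with the label 200, and TMM scaling 153 and 1774, then 0 and 0. In the DESeq2 fit at 12 h, 7312 sequences got no adjusted p with the label 200, against 319 with the label 150. Its 0 lower calls therefore do not show an absence of falls.

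These splits depend on the scaling, which shifts the median log2 change at 72 h with the label 200 by 4.45 (TMM) and 2.48 (DESeq2). Rises made up 2.02% of the calls at 72 h with the label 200, against 20.9% with TMM scaling (906 higher, 3420 lower) and 7.42% with DESeq2 (583 higher, 7279 lower). At 48 h they made up 2.85%, against 38.6% with TMM scaling and 14% with DESeq2, and at 24 h 1.14%, against 13.2% with TMM scaling. With the replicate block, calls at 12 h became 1051 higher and 6454 lower (label 150) and 948 and 6727 (label 200), and at 24 h with the label 200 669 and 6351. At 48 h with the label 200 they became 532 and 7885, and at 72 h 301 and 8276. At 12 h with the label 200, leaving out barcode 4 left 1758 calls and leaving out barcode 1, 2, 3 or 5 left 0.

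Grouped by design, the 3 largest shares of reads at 72 h with the label 200 were held by the sets in which leucine, methionine or proline replaces some glycines. Peptides in which some glycines became leucine went from 4.573 ± 0.668% of reads at 0 h to 44.04 ± 2.55% at 72 h with the label 200 and 35.13 ± 2.48% with the label 150. Methionine variants went from 4.13 ± 0.25% to 18.29 ± 3.27% and 18.95 ± 3.3%, and proline variants from 2.848 ± 0.168% to 8.155 ± 2.78% and 7.575 ± 1.97%. Cysteine variants went from 3.813 ± 0.39% to 0.1785 ± 0.0677% and 0.3503 ± 0.11%, so the gain did not extend to each substitution of glycine. Tryptophan and aspartate controls went from 0.6895 ± 0.225% to 3.482 ± 1.7% and 2.861 ± 1.5%; of 23 entries tested at the label 200, 7 rose and 13 fell, with a median log2 change of -6.19, and with TMM scaling 10 rose and 9 fell. Untreated cultures at 24 h held 7.434 ± 1.17% leucine, 5.766 ± 0.399% methionine, 2.888 ± 0.233% proline and 4.634 ± 0.703% cysteine variants.

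Of the sequences tested at the label 200, 39 of 98 leucine variants rose and 44 fell, 35 of 96 methionine variants rose and 29 fell, and 18 of 95 proline variants rose and 36 fell; with TMM scaling the rises were 59, 69 and 70 and the falls 24, 18 and 7, so the medians of the leucine and proline variants turn from -0.44 and -0.81 to 4.12 and 3.66. Cysteine variants fell in 95 of 98 with a median log2 change of -8.56 (the same with 2 unread sequences at their bound), and 0 rose by edgeR (0 at an unadjusted p under 0.05, 3 with TMM scaling and 2 with DESeq2). Partial tryptophan-to-tyrosine variants fell in 96 of 96. By camera 20 of 130 design sets stood apart, 15 upward and 5 downward relative to the other sequences. With an estimated correlation 16 did so. The adjusted p with that correlation was 7.42e-07 for methionine, 1.25e-05 for leucine, 1.68e-05 for proline, 0.00743 for cysteine and 0.00678 for partial tyrosine variants. The median log2 change of all tested sequences was -6.65, so a set can be upward while most of its sequences fell. In the blocked fit camera called 16 sets with the preset correlation and 0 with an estimated one, where the adjusted p was 0.11 for methionine and 0.162 for leucine variants. Full phenylalanine for tryptophan was upward there with the preset correlation, although 6 of its 97 tested sequences rose and 79 fell.

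**Figure D3:**
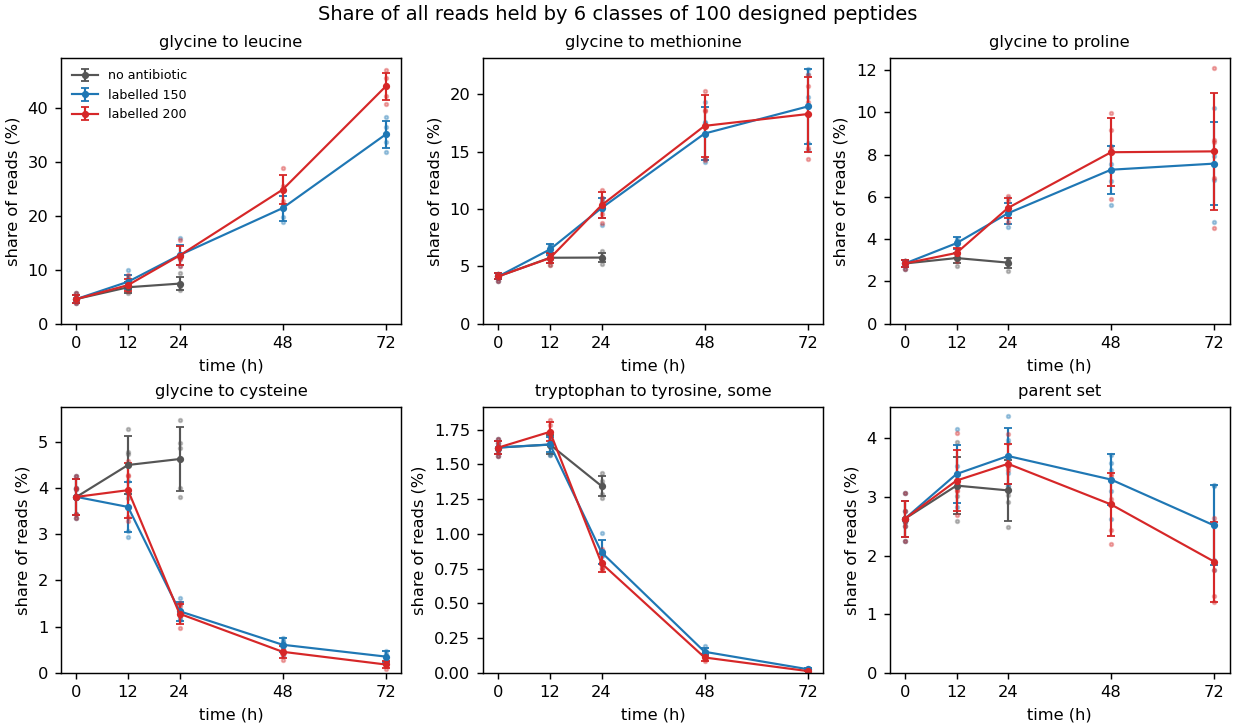
Share of reads (percent) against time in hours for 6 sets of 100 designed peptides, the parent set being set 32, with small points for barcodes and large points with bars for the mean and SD of 5. Leucine variants reach 44.04% and cysteine variants drop to 0.1785% at 72 h with the label 200.

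Each of 19 substitution series can be set against its own 100 parent peptides, which differ from it only by the named residues. Against their parents at the label 200 and 72 h, methionine in place of glycine changed the log2 abundance by 2.65 ± 0.11 (81 of 100 pairs higher), leucine by 2.09 ± 0.13 (69 of 100), proline by 2.06 ± 0.11 (80 of 100) and asparagine by 1.31 (75 of 100). Partial replacement of tryptophan by leucine (1.56) or phenylalanine (1.04, 71 of 100) was also positive. Cysteine for glycine gave -3.13 ± 0.11 (13 of 100 pairs higher), partial tyrosine for tryptophan -2.39 (16 of 100), serine for glycine -1.76 (22 of 100), full glutamate for aspartate -1.44 (32 of 100), valine for glycine -1.07 and full tyrosine for tryptophan -1.05. Each of these had an exact permutation p of 0.00794 (adjusted 0.0101, two-sided) with 5 of 5 barcodes in its direction.

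In all, 18 of the 19 series passed, and isoleucine for glycine did not (-0.32, adjusted exact p = 0.0952); the alternatives scale the prior count to the 2 groups compared alone, where its change was -0.38 (adjusted 0.0714). Against that it was 0.08 (adjusted 0.603) with a prior count of 10 and 0.72 (adjusted 0.0754) on summed reads, but -0.86 (adjusted 0.00838) with a prior count of 0.5, -0.34 (adjusted 0.0476) with a share of reads like the 0 h pool taken off and -0.98 (adjusted 0.0108) with the label 150. Full tyrosine for tryptophan moved with the prior count as well, from -1.17 on that scale to -0.14 (adjusted exact p = 0.142) with 10 and -2.15 (adjusted 0.00838) with 0.5. The sign-flip test within barcodes cannot go below 0.0625, so with the block 0 pass, and on summed reads 9 pass. Partial replacement of tryptophan by leucine (0.61, adjusted exact p = 0.137) or phenylalanine (0.38, adjusted 0.442) and asparagine (0.15, adjusted 0.771) or valine (-0.62, adjusted 0.255) for glycine do not pass on summed reads, nor do the 4 series below that turned direction or threonine for glycine (0.35, adjusted 0.377). Direction turned with summed reads for full replacement of tryptophan by leucine (-0.45 to 0.15) or phenylalanine (0.58 to -0.02) and of glycine by glutamine (0.34 to -0.52) or alanine (0.67 to -0.22). In untreated cultures at 24 h, cysteine gave 0.08 (adjusted exact p = 0.63), leucine 0.43 (0.163) and methionine 0.32 (0.0431) against their parents, while full tyrosine for tryptophan gave -1.97 (0.0377).

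**Figure D4:**
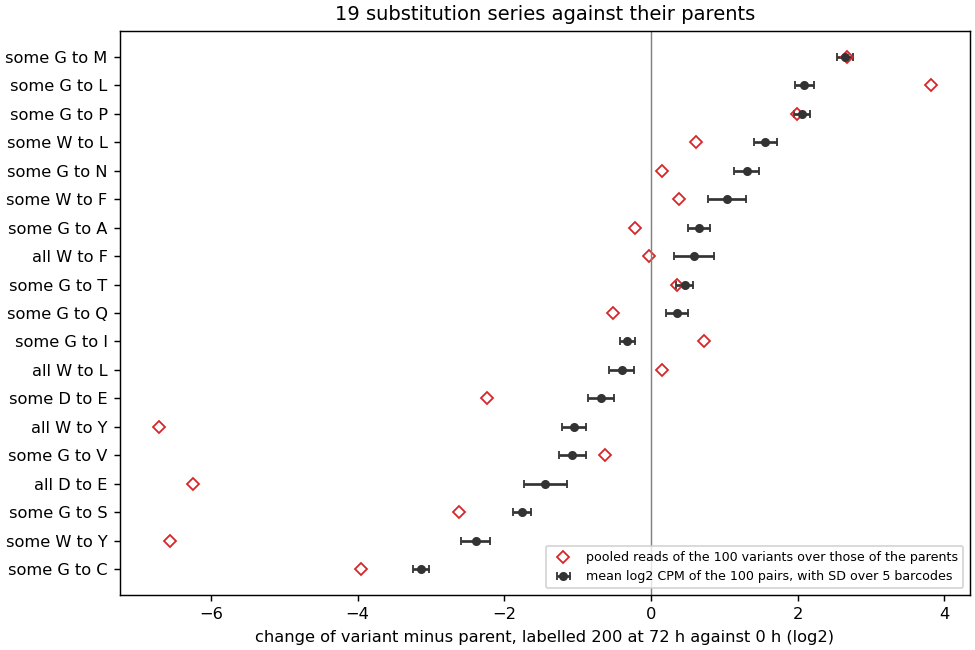
Change of each substitution series minus its parents (log2, 72 h with the label 200 against 0 h), with filled points and bars for the mean log2 CPM and SD over 5 barcodes and open diamonds for summed reads. Methionine, leucine and proline for glycine lie at 2.65, 2.09 and 2.06 and cysteine at -3.13 by the mean of logs, while full tyrosine for tryptophan lies at -1.05 by that measure and -6.71 on summed reads.

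Most of the activation domains carried as controls, which are mostly from natural proteins, were lost. Of 24 control peptides on 96 entries, 80 entries were tested at 72 h with the label 200, where 4 rose, 70 fell and 6 did not pass; with the label 150 the numbers were 3, 69 and 8. The 4 rises were 3 of 4 entries of the Oaf1 peptide, from the yeast regulator of the oleate response, with a median log2 change of 1.93, and 1 of 4 entries of a doubled VP16 motif, from the herpes simplex virus activator, with a median of 1.52. Oaf1 held 0.2 ± 0.0113% of reads at 0 h, 0.345 ± 0.0217% in untreated cultures at 24 h, 1.01 ± 0.0933% with the label 150 and 0.823 ± 0.0879% with the label 200 at 72 h. The doubled VP16 held 0.0403 ± 0.0201% at 0 h, and at 72 h 0.0649 ± 0.0572% with the label 150 and 0.125 ± 0.0956% with the label 200. With the label 200, all 4 entries of Oaf1 passed with the block, TMM scaling or DESeq2, as did 3, 4 and 4 entries of the doubled VP16.

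Among the control peptides named in file order, reads fell by different folds at the label 200, which are not a ranking of loss because lost entries kept reads there: stop-first entries, which encode no peptide, went from 0.4% to 0.00428%, and ESX kept 11 reads where the label 150 had 0. Gal4 (860-872), from the yeast galactose activator, went from 0.0549 ± 0.0214% of reads at 0 h to 0.00867 ± 0.00438% at 72 h with the label 200, 6.04 times lower on summed reads, whereas Gal4 (840-857) was 224 times lower (95% binomial interval 95.4 to 691, exact, from 5 reads left). This interval and those below cover counting error only, since PCR reads are not independent molecules, and over barcodes the share left was 3.71e-05 ± 5.38e-05%. The designed helix AH was 4.6 times lower. Of its entries 2 fell, and another changed by -1.69 on the log2 scale with an edgeR adjusted p of 0.0563, lower in 5 of 5 barcodes. With the replicate block all 3 tested entries of AH fell. EBNA2 was 153 times lower, Gcn4 158 times (76.2 to 394, 7 reads left), ESX 83.6 times, EKLF TAD1 65.8 times, hHSF1 58.1 times and KLF4 52.6 times. Gln3 kept 1 read of 461, 761 times lower with an interval of 136 to 30100. Each of these 10 controls was lower in 5 of 5 barcodes. Reads left at 72 h with the label 150 and the label 200 were 0 and 11 for ESX, 0 and 1 for Gln3, 10 and 42 for hHSF1, 6 and 19 for EBNA2, 4 and 5 for Gal4 (840-857), 7 and 7 for Gcn4, 162 and 72 for EKLF TAD1, 341 and 184 for KLF4, 983 and 850 for AH, and 1512 and 1188 for Gal4 (860-872). The 22 controls other than Oaf1 and the doubled VP16 fell in 70 of 72 entries tested, with 26 falling and 3 rising under TMM scaling. Among them the plant HSFA2 peptide held 0.0711 ± 0.0374% of reads at 0 h, 0.0613 ± 0.0835% with the label 150 and 0.0643 ± 0.104% with the label 200 at 72 h, and 3 of its 4 entries fell. Its barcodes moved apart: barcode 1 went from 0.0669% to 0.2502% with the label 200, and the others from 0.0282 to 0.13% down to 0.0101 to 0.0238%. All 366 tested entries of the wp-template sets fell, 218 with TMM scaling.

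The order of residues separated peptides of equal composition, a comparison chosen after the values had been seen. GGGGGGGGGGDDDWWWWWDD and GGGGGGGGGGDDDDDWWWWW each have 5 tryptophans and 5 aspartates on glycine; the first went from 0.191 ± 0.106% to 1.25 ± 0.651% of reads at 72 h with the label 200, the second from 0.175 ± 0.0673% to 0.00023 ± 0.000133%. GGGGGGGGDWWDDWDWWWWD, with 7 tryptophans and 5 aspartates, went from 0.0686 ± 0.0342% to 2.2 ± 1.31%, and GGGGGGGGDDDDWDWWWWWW from 0.175 ± 0.111% to 0.000281 ± 0.000262%. The alternating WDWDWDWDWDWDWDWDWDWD kept 0.0268 ± 0.0115% from 0.0604 ± 0.03%, and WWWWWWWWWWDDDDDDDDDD went from 0.0198 ± 0.00424% to 0.000184%. The log2 ratio of the first to the second of each pair was taken with 0.5 added to the reads. With the label 200 it changed by 12.26, 14.04 and 5.42 between 0 h and 72 h (two-sided exact permutation p = 0.00794, 5 of 5 barcodes for each pair). These changes rest on 30, 35 and 24 reads of the second peptides. With the label 150 they were 15.01, 16.73 and 9.61, on 1, 0 and 0 reads. Lost entries kept reads with the label 200, so the sizes depend on the label. The alternating peptide held 0.0655 ± 0.0307% at 72 h with the label 150. In untreated cultures at 24 h it held 0.0547 ± 0.0318%, whereas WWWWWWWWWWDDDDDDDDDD was down to 0.00362 ± 0.00359%. This pair thus moved apart without antibiotic as well, and its change cannot be put down to the antibiotic alone. The first pair held 0.26 and 0.237% there and the second 0.119 and 0.294%.

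The 32 sets built from glycine, tryptophan, aspartate and arginine vary several properties at once, and 2303 of their 2411 tested sequences fell at the label 200 while 10 rose. Set 32 was an exception in degree: 4 of its 97 tested sequences rose and 72 fell, and its share went from 2.629 ± 0.308% to 1.897 ± 0.682%, with a median log2 change of -4.05 that TMM scaling turns to 0.71; with TMM scaling 29 rose and 16 fell, and with DESeq2 22 rose and 42 fell. Between 0 h and 72 h, summed reads of sets richer in tryptophan and aspartate grew 27.37-fold against the poorer sets, those of sets without arginine 5.95-fold against sets with it, and those of sets with shorter tryptophan runs 2.28-fold (exact permutation p = 0.00794, adjusted 0.0132, 5 of 5 barcodes each). Equal numbers of both residues gave 1.35-fold (adjusted exact p = 0.0694) and a more C-terminal tryptophan 1.29-fold (exact p = 0.222). These are values for the label 200, where the mean of logs for the richer sets went the other way, by -1. With the label 150 at 72 h, summed reads grew 573.13-fold for richer sets, 10.36-fold without arginine and 1.91-fold for shorter runs. Lost entries kept reads with the label 200, which limits ratios against the poorer sets there. Untreated cultures at 24 h gave 5.27-fold, 2.24-fold and, for shorter runs, 0.93-fold (exact p = 0.206). The levels also differ in other residues: sets with shorter runs had 4.3 tryptophans on average against 5.37.

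In the sets that repeat a hydrophobic core between flanking residues, leucine and asparagine flanks gained within their sets. Peptides with 3 tryptophan cores and leucine before the core went from 9.06% to 40.7 ± 4.53% of the reads of that set at 72 h with the label 200 (log2 change in odds 2.78 ± 0.37, adjusted exact p = 0.0122), and leucine after the core from 13.7% to 37.7%. Around 3 leucine cores, asparagine before the core went from 4.48% to 39 ± 14.7% (3.82 ± 0.67, adjusted exact p = 0.0118) and tryptophan after it from 22.3% to 72 ± 19.2%. Around 3 phenylalanine cores, leucine before the core went from 9.73% to 28.1% (1.86, adjusted exact p = 0.0138). Tyrosine after or before a tryptophan core changed by -6.24 and -6.02 and cysteine after it by -6.15, valine after a leucine core by -6.55, and tyrosine before a phenylalanine core by -5.84. These sets as wholes lost share: tryptophan cores went from 5.518% to 1.309% of all reads, phenylalanine cores from 3.027% to 0.8189% and leucine cores from 2.837% to 1.740%. With the replicate block, 6 of 366 tested peptides with 3 tryptophan cores rose. So did 4 of 324 with 3 phenylalanine cores and 10 of 314 with 3 leucine cores. Values before and after a core come from the same peptides, so a few peptides can carry both and they are not separate effects.

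**Figure D5:**
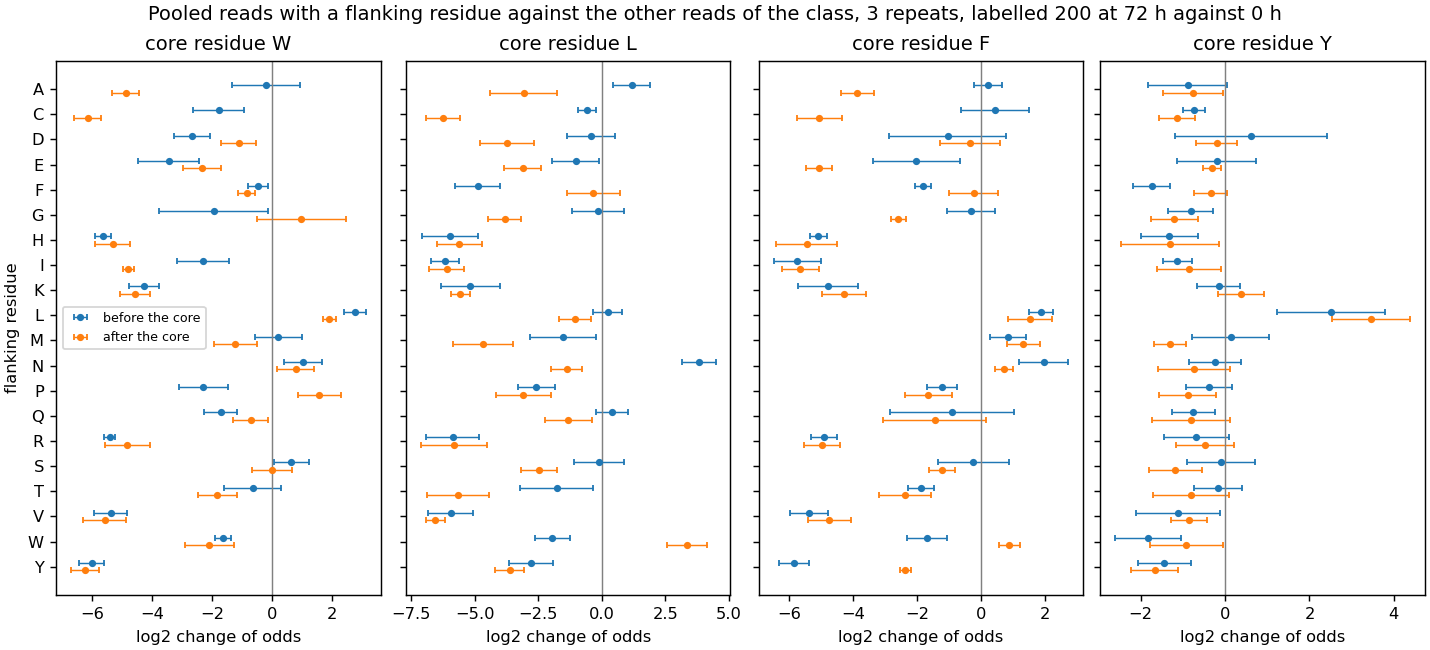
Log2 change in the odds of reads with each flanking residue against the other reads of its set (72 h with the label 200 against 0 h), before and after each repeated core, as means with SD over 5 barcodes. Leucine before the tryptophan core lies at 2.78 and tyrosine after it at -6.24.

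Planned sequence features ask which properties go with a gain. The feature called aliphatic residues counts leucine, isoleucine, valine and also methionine. These residues did not move alike in the substitution series: leucine and methionine for glycine gave 2.09 and 2.65, isoleucine and valine -0.32 and -1.07. At the label 200 and 72 h, peptides above the median in aliphatic residues gained 0.445 log2 units on those below it (0.581 ± 0.025 against 0.136 ± 0.034 at 0 h), peptides with more acidic and aromatic neighbours gained 0.333, and peptides with more acidic residues gained 0.144. The change was -0.261 for aromatic residues, -0.197 for basic residues and -0.182 for a more C-terminal aromatic position. Each had a two-sided exact permutation p of 0.00794 (adjusted 0.00964) with 5 of 5 barcodes in its direction. The value for acidic residues became -0.275 with a prior count of 10, -0.633 with no filter, -0.411 among peptides of 4 residues and 0.021 with a share of reads like the 0 h pool taken off, and that for adjacency -0.004, -0.118, -0.422 and 0.269. Among residues tested singly, leucine gave 0.571, tyrosine -0.496, proline -0.239 and phenylalanine 0.267, which turned to -1.629 on summed reads (exact p = 0.00794). Tryptophan gave -0.073 (adjusted exact p = 0.027), while camera put it up (adjusted p = 0.00107, 0.00585 with an estimated correlation). By camera tyrosine was down (adjusted p = 0.00229, 0.0222 with an estimated correlation), while leucine (0.0511, 0.0683), proline (0.664, 0.667) and phenylalanine (0.931, 0.919, direction down) were not past the threshold.

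By camera, acidic residues and adjacency were up (adjusted p = 0.000207 each, 0.00416 with an estimated correlation), basic residues down (0.00326, 0.0267), and aromatic residues up (0.0173, 0.0222), the opposite sign to their mean of logs. Aliphatic residues (0.0511, 0.0749) and aromatic position (0.931, 0.919) were not past the threshold by camera. These directions are relative to the peptides on the other side of each split and do not show a gain of share. On summed reads the changes were 6.805 for acidic, 2.695 for aliphatic, -4.731 for basic residues and 3.015 for adjacency, while aromatic residues (2.326) and aromatic position (0.415) turned positive. Within barcodes the sign-flip test cannot go below 0.0625.

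At 24 h the antibiotic can be set against untreated cultures of the same age. With the label 150, 1665 of 4416 sequences were lower than in untreated cultures and 0 higher by edgeR, with 13 higher at an unadjusted p under 0.05, 22 by DESeq2 and 0 with TMM scaling. With the label 200, 379 of 4695 were lower and 0 higher, with 61 higher at an unadjusted p under 0.05, 50 by DESeq2 and 0 with TMM scaling. Against their parents and from 0 h to 24 h, cysteine variants changed by -3.72 ± 0.18 with the label 150 and by 0.08 ± 0.06 in untreated cultures. With the block the calls became 846 higher and 2572 lower (label 150) and 787 and 1640 (label 200). Without barcode 1, 2 or 5 the label 200 had 0 calls, and without barcode 3 or 4 it had 2.

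The doses shared most of their calls. Among the 8702 sequences tested with both labels at 72 h, 171 rose with the label 150 and 165 with the label 200. Of these rises 144 were shared, where independent lists would share 3.2. In the same sequences 7711 and 7934 fell, of which 7698 were shared, against 7030.5. Log2 changes correlated across 8702 sequences with r = 0.883 (rho = 0.639), with the same sign in 98.2%; sequences are not independent replicates. Both use the 0 h libraries: unchanged groups gave r = 0.512, rho = 0.494 and the same sign in 67.2% in simulation, and the covariance was 7.594 against 0.398 simulated, a difference of 7.196. With the 0 h barcodes split between the doses r was 0.857.

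Between the doses at 72 h, edgeR called 0 of 1486 sequences different, with 0 higher at an unadjusted p under 0.05, and 0 were called with TMM scaling or by DESeq2. With the replicate block 141 were higher and 1119 lower with the label 200. No sequence met the naming rule here. The leading peptide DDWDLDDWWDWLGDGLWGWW stood at 19.49 ± 5.707% with the label 200 and 10.76 ± 3.425% with the label 150.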

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

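The tests in this part were chosen after the results were seen, apart from the search for outlying barcodes. By chance alone about 1 in 20 groups would show an outlying barcode, and 14 were found in 138 groups of 5, each with a gap above 0.71 of the range.

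Stop-first entries lost share in untreated cultures by 12 h, where no selection by antibiotic is labelled. A few sequences taking most of the reads would give an equal loss in all other entries, but the log2 ratio of stop-first to set 32 reads changed by -3.38 (SD 0.25, lower in 5 of 5 barcodes). Base composition of the tag was tested within 4 bins of GC content, where stop-first entries changed by -2.05 to -2.88 relative to set 32 entries, which speaks against it as the whole cause. Antibiotic at the labelled dose in the untreated cultures is argued against by the cysteine variants, which changed against their parents by 0.08 (SD 0.06) there and by -3.72 (SD 0.18) with the label 150 at 24 h. Sets of peptides with 1 core, whose tags have 20 bases where those of stop-first entries have 80, lost share in a like degree by 12 h (phenylalanine cores from 0.382% to 0.0492%, stop-first entries from 0.4% to 0.0471%), so the loss was not particular to stop-first entries or to their tag; its cause stays open, and no biological explanation was tested.

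Stop-first and other lost entries kept reads in the libraries labelled 200 that they lost with the label 150. Lower depth with the label 150, which holds of 72 h but not of 24 h or 48 h, would leave 398 stop-first reads at 72 h, and 0 were found. If the cause were slower loss from the culture sampled at 12 h, entries with no read at 12 h should stay near 0, but they returned at 0.91 ± 0.24 of the level of entries with 11 to 50 reads there at 48 h and 1.09 ± 0.18 at 72 h; the 24 h value, 0.89 ± 0.70, did not decide alone, so the later times were then used. Material in proportion to the 0 h pool would make up 13.9 ± 3.28% of reads at 24 h, 4.16 ± 0.659% at 48 h and 1.08 ± 0.361% at 72 h if every stop-first read came from it; other entries with no read at the label 150 reached 0.99 ± 0.26, 0.98 ± 0.09 and 1.04 ± 0.21 of the reads this gives where they had 15 to 60 reads at 0 h in a barcode, but 0.40 ± 0.12, 0.26 ± 0.05 and 0.26 ± 0.06 where they had over 200, which speaks against it as the whole cause. The source of these reads stays open, and no biological explanation was tested.

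Abundance at 0 h went with the later change in untreated cultures, both across entries and across 69 design sets (rho = 0.72). Chance sampling of entries at 0 h was tested by taking abundance from barcodes 1 and 2 and the change from the other barcodes, where rho across 12400 entries was 0.27, which argues against it as the whole cause. Base composition of the tag was tested within 6 bins of GC content. In the large bins, of 2181 to 4555 entries, rho was 0.19, 0.2, 0.22 and 0.27. A positive relation thus remained within these bins. In the small bins rho was -0.85 in 33 entries that are all stop-first and -0.08 in 50 entries. The rule asked for rho above 0.2 in every bin to speak against GC content of the tag. It was not met, so the test did not decide and GC content stays open. Growth before 0 h and the synthesis of the pool may each contribute and cannot be measured apart here.

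In libraries with the label 200 at 48 h, barcode 4 had 0.0208% stop-first reads against 0.0145 to 0.0163% in the others. In untreated cultures at 24 h, barcode 2 had 2.48% proline variants against 2.91 to 3.07%. With the label 150 at 72 h, barcode 1 had 0.85% Oaf1 reads against 1.03 to 1.08%. With the label 200 at 72 h, barcode 3 stood apart in the acidic measure, 1.74 against 1.68 in the others, and in the basic measure, -1.2 against -1.16 to -1.14. The fourth entry of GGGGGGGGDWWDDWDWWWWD had 24900 CPM in barcode 2 with the label 150 at 72 h against 1280 to 7970. In barcode 1, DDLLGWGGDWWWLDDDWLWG had 817 CPM at 0 h against 137 to 273, and 20400 with the label 150 at 72 h against 4850 to 7850. In the same barcode, the first entry of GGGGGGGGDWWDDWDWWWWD had 686 CPM at 0 h against 51.2 to 231, 17200 with the label 150 at 72 h against 779 to 4360, and 23500 with the label 200 against 1080 to 6630. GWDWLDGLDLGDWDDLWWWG had 668 CPM there at 0 h against 81.4 to 166, 16700 with the label 150 against 878 to 4400, and 18600 with the label 200 against 983 to 4540.

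Set directly against each other at 72 h, label 200 minus 150, the doses differed by -0.51 for aromatic residues (adjusted exact p = 0.0181, 5 of 5 barcodes) and by -0.16 for aromatic position (adjusted exact p = 0.0476, 5 of 5 barcodes). These values come from the 1486 sequences tested between the doses, where 1433 peptides lay above and 41 below the median in aromatic residues, and 668 and 681 in position. The changes from 0 h, on larger sets of sequences, were -0.261 with the label 200 and 0.023 with the label 150 for aromatic residues and -0.182 and -0.122 for position, and their difference on those sets was not tested.

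Other splits of the 10 libraries of each comparison were counted, 100 per comparison, the real split included. In 12 of the 13 comparisons 1 split of 100, the real split, gave as many calls. This speaks against a chance split of the barcoded libraries there. Chance differences between cultures cannot be tested this way, because the barcodes of a sample are not known to be separate cultures. The real counts were 2420 and 2399 in untreated cultures at 12 and 24 h, against at most 33 and 34 in the other splits; 4857, 6392, 7417 and 7882 with the label 150 against 30, 4, 2 and 0; 3103, 3598, 7706 and 8151 with the label 200 against 33, 3, 1 and 1; and 1665 and 379 against untreated cultures at 24 h, against 1 and 1. Between the doses the real count was 0, the highest other 2, and 100 of 100 splits gave as many, as any split must beside a count of 0, so this count decides nothing; with the replicate block 1260 of 1486 sequences were called there. Among the 16 splits that part every pair of barcode numbers, the highest other count was 0 or 1.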

How the results depend on the processing

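Fits that take off the 0 h-like share, peptides of 4 residues only, summed reads and the substitution series were chosen after the data were seen; the other settings were planned. Among counts per comparison 80 settings stayed within 1.5 times and 68 did not. The cause was not tested, save that the minimum of 50 and the left-out barcodes test or use fewer values. Untreated 12 h (2420): TMM 0, no filter 4432, minimum of 50 0, replicate block 7494, all groups in 1 fit 0, DESeq2 793, leave-one-out 693 to 1729. Untreated 24 h (2399): TMM 357, no filter 4922, minimum 0, block 7535, all groups 11, leave-one-out 1085 to 1796. With the label 150 at 12 h (4857): TMM 1927, no filter 7779, minimum 150, block 7505, all groups 357. At 24, 48 and 72 h (6392, 7417, 7882): minimum 1220, 2137 and 2573, all groups 2758, 3682 and 4194. With the label 200 at 12 h (3103): TMM 0, no filter 4683, minimum 0, block 7675, all groups 0, DESeq2 760, where 7312 sequences got no adjusted p, leave-one-out 0 to 1758. At 24 h (3598): TMM 1991, no filter 5464, minimum 690, block 7020, all groups 1885. At 48 and 72 h (7706, 8151): TMM 2795 and 4326, minimum 2356 and 2784, all groups 3837 and 4406. Against untreated 24 h, label 150 (1665): no filter 3347, minimum 450, block 3418; label 200 (379): minimum 131, block 2427, all groups 817, 0 h-like share off 1184, DESeq2 745, leave-one-out 0 to 2. Between doses (0): block 1260, all groups 16, 0 h-like share off 19, leave-one-out 0 to 0. Leave-one-out ranges elsewhere were 3668 to 4476, 5812 to 6389, 6879 to 7449 and 7362 to 7922 (label 150), 2508 to 2916, 7148 to 7712 and 7670 to 8214 (label 200 from 24 h) and 1291 to 1575 (150 against untreated).

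Aliphatic residues (0.445) kept their direction in every setting tried; peptides of 4 residues hold none and gave no value. Reversals were: acidic, prior count 10 -0.275, no filter -0.633, peptides of 4 residues -0.411; aromatic, prior 0.5 0.126, label 150 0.023, summed reads 2.326, Spearman 0.037; basic, prior 10 0.107, 4 residues 0.264; adjacency, prior 10 -0.004, no filter -0.118, 4 residues -0.422; position, 4 residues 0.12, summed reads 0.415. Values no longer past the threshold were acidic with the 0 h-like share off (0.021), aromatic with a minimum of 50 (-0.047), position against untreated 24 h (-0.093), and with the replicate block, where an exact p cannot go below 0.0625, acidic 0.144, aromatic -0.261, aliphatic 0.445, basic -0.197, adjacency 0.333 and position -0.182. Leave-one-out gave 0.154 to 0.172, -0.279 to -0.216, 0.445 to 0.462, -0.227 to -0.194, 0.346 to 0.362 and -0.195 to -0.175 in that order. Design sets (20) became 33 with TMM scaling. The dose correlation became 0.857 with split 0 h barcodes, 0.929 with the minimum of 50 and 0.694 at 24 h. Substitution series passing (18) became 0 with the block and 9 on summed reads, 16 to 17 in leave-one-out; full tryptophan to leucine reversed with prior 10 (0.04) and summed reads (0.15), full tryptophan to phenylalanine with the label 150 (-0.39) and summed reads (-0.02), glycine to glutamine with the label 150 (-0.03) and summed reads (-0.52), glycine to alanine on summed reads (-0.22). Named sequences kept direction and threshold in 374 settings; 2 got no adjusted p from DESeq2, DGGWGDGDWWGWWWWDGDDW and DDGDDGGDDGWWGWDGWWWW. Single series otherwise kept both in 166 settings, lost the threshold in 33 and gained it in 3. Depth limits the lost sequences, whose folds are bounds.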

Other observations

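Peptides with tyrosine cores lost almost all of their share while leucine flanks gained within the set, in values chosen after the results were seen. The set with 3 tyrosine cores went from 2.075% of reads at 0 h to 0.02697% at 72 h with the label 200. Lost entries kept reads there, with stop-first entries going from 0.4% to 0.00428%, which limits the values of so small a remainder. With the label 150 at 72 h, where stop-first entries had no read, the set with 3 tyrosine cores held 0.03351%. With the replicate block, 0 of 327 tested peptides rose in this set. Within it, leucine after the core went from 6.73% to 44.7 ± 16.3% of the set's reads (log2 change 3.46, adjusted exact p = 0.0244) and leucine before the core from 9.07% to 37.7% (2.52). Around phenylalanine cores, asparagine before the core went from 2.74% to 10.6% (1.95, adjusted exact p = 0.0227), and around tryptophan cores proline after the core went from 8.02% to 21.7% (1.59).

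Among sets that repeat a core, the set with 3 tryptophan cores kept more of its share than those with 1 or 2. The set with 1 tryptophan core went from 0.5204% of reads at 0 h to 0.07313% in untreated cultures at 24 h and 0.00577% at 72 h with the label 200. The set with 2 tryptophan cores went from 2.416% to 1.739% and 0.02141%, and that with 3 from 5.518% to 6.243% and 1.309%. The set with 1 phenylalanine core went from 0.382% to 0.03749% and 0.004452%. With the label 150 at 72 h the sets with 1, 2 and 3 tryptophan cores held 0.000337%, 0.0236% and 2.315%.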
